A study of Mus musculus with 300 samples.

How the data were processed

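Total RNA from the livers of single mice was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per animal, so that each replicate is a separate animal per the labels. The deposited values are log2 expression values per Ensembl transcript, made by the authors with the RMA method in the affy package under R 2.11, per the submitters' processing notes and the series title. RMA corrects the background, quantile-normalizes the probe intensities over the arrays and combines the probes of a transcript by median polish. The Ensembl release and the genome build are not given in the sources used here. The values ran from 4.66 to 13.60, no array matched another (the highest correlation between 2 arrays was 0.995), and all 34406 transcripts were kept.

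Rows carry Ensembl transcript identifiers and were not paired with gene names here, because the gene table used (assembly GRCm38.p6) lists none of these identifiers: 0 of 34406 were named. The gene lists, cell type markers and the rule for naming genes by symbol, which were fixed before the data were examined, were therefore not applied. In their place each transcript was its own feature, and the text names at most 2 transcripts in each direction of a comparison, those with the greatest absolute difference among the called ones (for the strain difference, only those without overlap between MRL and SM animals in either sex, and for the parental and F1 sex difference those named in F2). The restriction of the segregation counts to autosomes was not applied for the same reason.

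Groups were taken from the labels: strain or generation, and sex. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options), with Benjamini-Hochberg adjustment over all transcripts and a threshold of 0.05. One fit of the 18 MRL, SM and F1 animals with a mean for each of 6 groups gave the strain difference (MRL minus SM) over both sexes and in each sex, the strain by sex interaction (male minus female strain difference), F1 minus the mean of the parental groups, and the sex difference (male minus female). F2 animals were left out of that fit because segregation adds to their spread. The F2 sex difference was fitted in 282 animals with batch as a fixed term. The 18 animals were spread over 10 batches, with at most 2 arrays of a group in a batch. MRL and SM animals of the same sex met in 1 batch for females, with 1 animal of each strain and so no test, and in 2 batches for males, which were compared with batch in the fit.

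For the F2 variance ratio, batch effects estimated in F2 were subtracted from the 18 animals, and each transcript's residual variance in F2 was divided by that of the 18 animals. Uncalled transcripts were weighted over 20 bins of mean expression to match the called ones. For segregation, sex and batch effects estimated in F2 were subtracted from all arrays, and each F2 animal was assigned to the nearest of the MRL, F1 and SM mean levels.

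The fits were tested on simulated data with 50 changed transcripts per size among 34406. For the strain difference over both sexes 54% of changes of 0.25 and 92% of changes of 0.5 log2 units were recovered. For the interaction these were 8% and 56%, with 96% at 1 log2 unit, for F1 against the parental mean 70% and 98%, and for the sex difference in the parental and F1 animals 72% and 98%. For the F2 sex difference 46% of changes of 0.05 and 96% of changes of 0.1 were recovered. No recovered change had the wrong sign. With simulated loci in the ratio 1:2:1, parental levels 8 SD apart and the middle level exactly midway, the median share nearest the middle level was 48.9%. Middle levels away from the midpoint were not simulated.

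The alternatives tried were a filter on transcripts above the median mean, centring of arrays, quantile normalization of the deposited columns, the trend and robust options, several treatments of batch, only the compared groups, the animal number as a block, and leaving out each of the 18 animals. After the data were seen, a correction for the spread of each array, batch as a fixed term in the 18 animals, the males of the shared batches and fits without the libraries of doubtful sex transcripts were added. Mean values over the rows of a gene were not computed, since rows were not assigned to genes. Genotypes and phenotypes of the F2 animals were not used here. Figures were drawn with matplotlib 3.10.9.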

Results

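Liver RNA from 300 mice was measured on Affymetrix Mouse Gene 1.0 ST arrays, which read whole transcripts with probes along the exons. The inbred strains MRL/MpJ (MRL) and SM/J (SM) were crossed, with SM as the father, and the F1 offspring were intercrossed to give F2 animals whose alleles segregate. The parental strains and the F1 generation each gave 3 females and 3 males, 18 animals in all, and F2 gave 135 females and 147 males. All mice were 13 weeks old, and the arrays were run in 14 batches of 2 to 25 arrays. The table holds 34406 transcripts on a log2 scale, with values between 4.66 and 13.60, and the number of arrays per group limits the precision. Sex was the largest source of variation over all arrays: the first principal component took 29.3% of the variance, and sex accounted for 93.9% of that component. The second component took 14.8% of the variance and followed a property of the arrays. The spread of each array, the SD over its transcripts, accounted for 94.7% of that component and sex for 1.0%. This spread also differed between the groups, as given below.

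The sex labels were checked with 51 transcripts whose MRL and SM animals were separated by sex by over 1 log2 unit, 30 higher in males and 21 higher in females. The mean of these transcripts, scaled so that parental females average -1 and parental males 1, ran from -1.38 to -0.69 in F2 libraries labelled female and from 0.51 to 1.13 in those labelled male, 5 libraries aside. The library labelled F1 male replicate 1146 scored -0.97, and 50 of its 51 sex transcripts lay nearer the female mean, while the other F1 males scored 0.93. The transcript ENSMUST00000082214_at, at 6.18 ± 0.61 (SD, n = 147) in F2 males and 11.91 ± 0.16 (SD, n = 135) in F2 females, stood at 11.79 in that library. The 5 F2 libraries set aside lay between the sexes. They were labelled female replicates 2293, 2116, 2295 and 2122, at -0.59, -0.05, -0.09 and -0.40, and male replicate 2308, at -0.04. All libraries were kept under their labels, and results that use the F1 males include the library labelled F1 male replicate 1146.

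**Figure D1:**
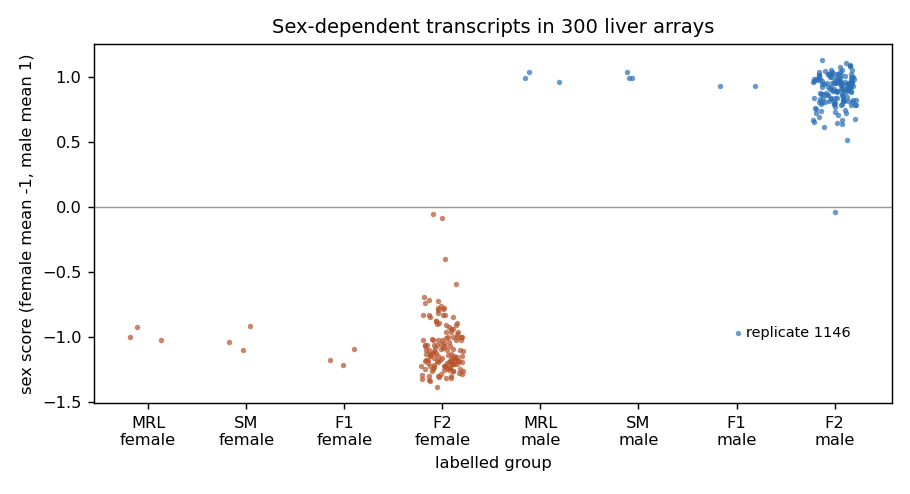
Sex score of each of the 300 arrays (1 point per array) by labelled group, on a scale where the mean of the parental females is -1 and of the parental males 1. Replicate 1146, labelled F1 male, sits at -0.97 among the females, and 5 F2 arrays sit between -0.65 and 0.4.

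The strain comparison asked which liver transcripts differ between the MRL and SM parents. ENSMUST00000044547_at was higher in MRL by 2.55 ± 0.08 log2 units (SE, 6 animals per strain), with 9.22 ± 0.19 (SD, n = 3) in MRL females and 6.54 ± 0.15 (SD, n = 3) in SM females. ENSMUST00000047134_at was higher in MRL by 2.59 ± 0.24 (SE), at 8.59 ± 0.19 in MRL females and 9.22 ± 0.15 in MRL males against 6.32 in SM animals of either sex. Its SE takes in the spread of the F1 animals, with an SD of 1.11 (n = 3) in F1 females. In the other direction, ENSMUST00000078869_at differed by -3.41 ± 0.12 log2 units (SE), 10.6-fold higher in SM, where it reached 12.52 ± 0.04 (SD, n = 3) in females. ENSMUST00000026012_at differed by -2.89 ± 0.31 (SE), and its SM level was 10.87 ± 0.60 (SD, n = 3) in females and 7.60 ± 0.19 in males. The limma adjusted p was 2.71e-13, 7.51e-07, 2.77e-12 and 5.48e-06 for these transcripts. MRL and SM animals did not overlap within either sex for any of them, which was a condition of their choice and not a separate result.

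**Figure D2:**
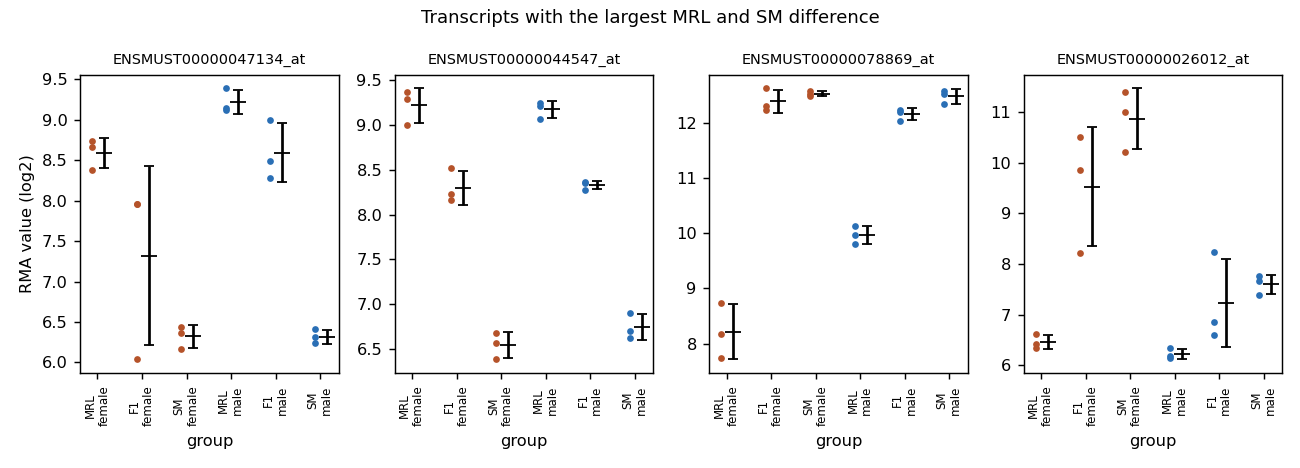
RMA value (log2) of the transcripts with the greatest strain difference in each direction, for each of the 18 MRL, F1 and SM animals (points; females brown, males blue), with the mean and SD of each group of 3 in black. MRL and SM animals of the same sex do not overlap, as the choice of these transcripts required. The F1 animals of ENSMUST00000078869_at lie near the SM level. The group labelled F1 male includes replicate 1146.

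Across the array, 3552 of 34406 transcripts differed between the strains at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 2091 higher in MRL and 1461 higher in SM. The difference was at least 1 log2 unit in 122 of them, 56 higher in MRL and 66 in SM, and the median size was 0.27 log2 units. Among all 34406 transcripts, called or not, MRL and SM animals did not overlap within either sex in 3276, where chance separates 3 from 3 animals in each of 2 sexes in 1% of transcripts. With batch as a random block the count was 3435, and with batch as a fixed term, which leaves 3 residual degrees of freedom, it was 2249, with 45.0% higher in MRL in place of 58.9%. The correlation within batches estimated for the random block was negative (-0.08), so that fit took up no shared batch shift. The random block counts of the other comparisons come from the same fit and are no check on batch either. A sequence difference between the strains under a probe also changes an array value, and no probe sequence was used here to tell such transcripts apart.

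Within each sex the same question was put to 3 animals against 3. In females 2761 transcripts differed, 1159 higher and 1602 lower in MRL, and in males 2225 differed, 1614 higher and 611 lower. ENSMUST00000078869_at differed by -4.31 ± 0.17 log2 units (SE) in females and -2.51 ± 0.17 in males. ENSMUST00000026012_at differed by -4.41 ± 0.44 (SE) in females, the greatest difference in that sex. Both sexes shared 838 called transcripts, 828 of them in the same direction, where independent lists of these lengths would share 82.8 in the same direction. Both lists use the same estimate of each transcript's spread, which by itself makes them more alike than independent lists. Over all transcripts, which are not independent replicates, the strain differences of females and males correlated with r = 0.39.

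The female count was 1361 without MRL female replicate 2, 1732 without SM female replicate 3, 1776 without SM female replicate 2 and 1758 without MRL female replicate 1. The male count was 1233 without MRL male replicate 7 and 1302 without SM male replicate 6. With batch as a random block 2659 transcripts were called in females and 2098 in males, with batch as a fixed term 980 and 1220, and a fit of all 300 animals with batch as a fixed term called 1501 and 1139, where ENSMUST00000078869_at no longer passed in males (-2.43 log2 units, adjusted p = 0.148). The 3 MRL and 2 SM males of the 2 batches that hold both strains, with batch in the fit, gave 1629 calls, 1263 of them among the 2225. Of the called transcripts 42.0% were higher in MRL in females and 72.5% in males, and these shares became 53.9% and 59.9% once the slope of each transcript on the spread of its array was subtracted. The spread of an array, the SD over its transcripts, averaged 1.24 in MRL females and 1.30 in MRL males, against 1.27 and 1.26 in SM.

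Whether the strain difference itself depended on sex was tested as an interaction. ENSMUST00000086148_at was 10.51 ± 0.61 (SD, n = 3) in SM females and 7.52 ± 0.26 in MRL females, while males of both strains stayed at 5.64 ± 0.14 (SM) and 5.52 ± 0.14 (MRL). ENSMUST00000108522_at had the same form, at 8.84 ± 0.94 in SM females, 6.09 ± 0.05 in MRL females and 5.54 and 5.49 in SM and MRL males. The reverse held for ENSMUST00000095784_at, which reached 8.47 ± 0.31 (SD, n = 3) in SM males against 6.70 ± 0.33 in MRL males and 6.14 and 6.20 in SM and MRL females. ENSMUST00000027467_at was likewise raised in SM males only, at 7.95 ± 0.26 against 6.40, 6.33 and 6.41 in MRL males, SM females and MRL females. The differences between the male and the female strain difference were 2.88 ± 0.47, 2.70 ± 0.53, -1.83 ± 0.20 and -1.64 ± 0.18 log2 units (SE), with limma adjusted p of 0.0139, 0.0421, 9.58e-04 and 9.58e-04.

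In all, 76 transcripts passed the interaction test, 45 with a higher and 31 with a lower MRL minus SM difference in males. The strain difference was called in females alone for 34 of them, in males alone for 29, in both sexes in the same direction for 5 and in opposite directions for 8. The count depended on single animals: it was 201 without the library labelled F1 male replicate 1146, which enters only the shared spread, 225 without SM female replicate 1 and 134 without SM male replicate 8. It was 28, 30 and 43 without MRL male replicates 8, 7 and 6, 37 and 46 without SM male replicates 6 and 7, 36, 46 and 50 without MRL female replicates 2, 1 and 3, and 39 and 50 without SM female replicates 2 and 3. With batch as a random block, 55 transcripts were called, in the fit of all animals with batch 25, with batch as a fixed term 35 (15 of them among the 76) and with only the compared groups 266. The share with a higher difference in males turned from 59.2% to 40.7% once the array spread slope was subtracted. With batch effects estimated in F2 subtracted, ENSMUST00000086148_at kept a difference of 2.67 ± 0.57 and ENSMUST00000108522_at of 2.58 ± 0.57 log2 units (SE) but did not pass (adjusted p = 0.0732 and 0.0897). ENSMUST00000095784_at, at -1.83 log2 units with batch as a fixed term, did not pass there (adjusted p = 0.095). ENSMUST00000108522_at also lost its call when single animals were left out.

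The F1 animals were compared with the mean of the parents to ask how the strain differences are inherited. Of 575 strain-called transcripts with a difference of at least 0.5 log2 units, 422 (73.4%) had an F1 mean in the middle part of the parental interval, between 0.25 and 0.75 on a scale with SM at 0 and MRL at 1. The median F1 position was 0.49, with quartiles of 0.35 and 0.64, and it was 0.52 without the library labelled F1 male replicate 1146. The F2 mean, with equal weight for each sex, had a median position of 0.50 for the same transcripts.

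Departures of F1 from the parental mean were few, and 13 of 34406 transcripts passed the limma test, 7 higher and 6 lower. The parental mean, like the positions above, was taken on log2 values. A level midway between the parents on the unlogged scale lies above that mean, most of all where the strains differ widely. Whether F1 departs from the unlogged midpoint was not tested. ENSMUST00000078869_at was 1.48 ± 0.10 log2 units (SE) above the parental mean (adjusted p = 1.09e-06), at 12.39 ± 0.21 in F1 females and 12.15 ± 0.10 in animals labelled F1 male (SD, n = 3 each), close to the SM level of 12.52 and 12.47. ENSMUST00000000755_at was 0.57 ± 0.08 above the parental mean (adjusted p = 0.0112), with 8.33 ± 0.14 in F1 females against 7.89 ± 0.13 in MRL and 6.79 ± 0.36 in SM females, while animals labelled F1 male stood at 7.99 ± 0.20 against 7.78 ± 0.10 in MRL and 7.88 ± 0.05 in SM males. Whether this departure differs between the sexes was not tested. ENSMUST00000099390_at lay below the parental mean, by -0.48 ± 0.05 log2 units (adjusted p = 6e-04). Its highest F1 value was 7.85 and its lowest parental value 7.94, so that all 6 F1 animals were below all 12 parental animals. ENSMUST00000095784_at differed by -0.69 ± 0.09 (adjusted p = 0.00265), and F1 males, at 6.30 ± 0.18, lacked the high level of SM males.

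At an unadjusted p under 0.05, 3264 transcripts differed from the parental mean. The count of 13 became 139 without the animal labelled F1 male replicate 1152, 20 without replicate 1146, 7 without F1 female replicate 1150 or SM male replicate 7, and 6 without F1 female replicate 1149, MRL female replicate 1 or MRL male replicates 7 and 8. With batch as a random block it was 12, with batch as a fixed term 30 (3 of them among the 13), and with the batch effects estimated in F2 subtracted 7. The share above the parental mean turned from 53.8% to 28.6% with the array spread slope subtracted and to 40% after quantile normalization. Without F1 female replicate 1150, ENSMUST00000000755_at stood 0.53 log2 units above the parental mean and no longer passed (adjusted p = 0.0635), and in the fit of all 300 animals with batch none of the 4 named transcripts passed. In the fit with batch as a fixed term ENSMUST00000095784_at (-0.69 log2 units, adjusted p = 0.245) and ENSMUST00000099390_at (-0.40, adjusted p = 0.189) did not pass.

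The sex comparison was made in F2, where 147 males stood against 135 females, and separately in the 18 parental and F1 animals. ENSMUST00000082214_at was higher in F2 females, with a male minus female difference of -5.72 ± 0.06 log2 units (SE), and ENSMUST00000092597_at differed by -5.25 ± 0.09 (SE), from 10.72 ± 0.89 (SD, n = 135) in females to 5.45 ± 0.46 (SD, n = 147) in males. The last SD was 0.11 without male replicate 2308, which lies between the sexes and stood at 10.78. ENSMUST00000084343_at was higher in F2 males by 4.89 ± 0.08 and ENSMUST00000094887_at by 4.30 ± 0.06 log2 units (SE), reaching 11.22 ± 0.18 and 10.11 ± 0.57 (SD, n = 147) in males. In the parental and F1 animals the same transcripts differed by -5.19 ± 0.53, -4.84 ± 0.53, 4.47 ± 0.45 and 4.01 ± 0.44 log2 units (SE). Without the library labelled F1 male replicate 1146 these became -5.83, -5.48, 5.00 and 4.54.

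In F2, 15478 of 34406 transcripts differed between the sexes (limma adjusted p under 0.05, batch in the fit), 8143 higher in males and 7335 higher in females. Most of these differences were small: the median was 0.067 log2 units, and 97.8% were under 0.5. At least 0.5 log2 units separated the sexes in 343 transcripts, 164 higher in males and 179 in females, and at least 2 units in 39, 18 higher in males and 21 in females. Within the 13 batches that hold both sexes, 1103 to 4415 transcripts were called. When each batch was held out and transcripts were called in the others, 82.2% to 91.2% of those calls had the same direction in the batch held out, where no change would give 50%. Of the calls of at least 0.5 log2 units, 338 to 348 per batch held out, at most 2 had the other direction. Centring each array on its median raised the share higher in males from 52.6% to 67.9%, so that the direction balance of the small differences rests on the scaling.

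The 18 parental and F1 animals gave 3109 transcripts with a sex difference, 1700 higher in males and 1409 in females. Of these, 2941 were also called in F2 and 2937 of them had the same direction, where independent lists would share 703 in the same direction. Over all transcripts the differences in the separate sets of animals correlated with r = 0.93. The 18 animals gave 3105 transcripts with batch as a random block and 3723 without the library labelled F1 male replicate 1146. A fit with batch as a fixed term gave 941, of which 40.2% were higher in males in place of 54.7%.

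**Figure D3:**
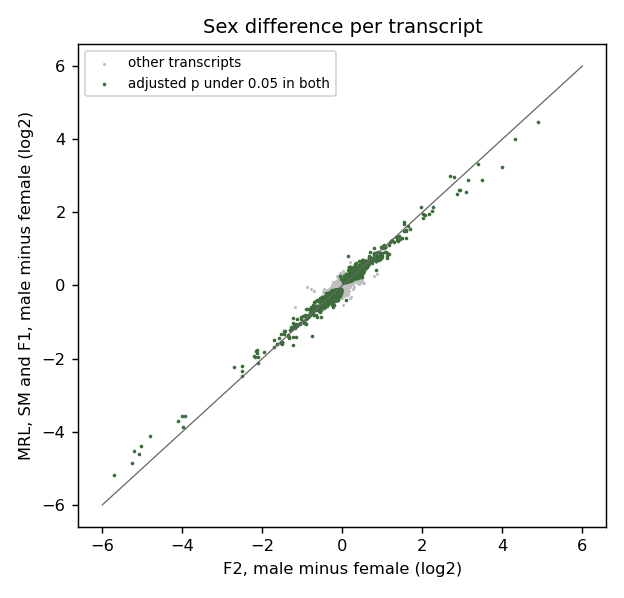
Male minus female difference (log2) of each of the 34406 transcripts in F2 (horizontal axis, 147 males and 135 females) and in the MRL, SM and F1 animals (vertical axis, 9 labelled males and 9 females), with the line of equality. Green points passed an adjusted p under 0.05 in both sets. The transcripts with the greatest differences lie slightly nearer 0 on the vertical axis, which includes the library labelled F1 male replicate 1146.

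Segregation of parental alleles in F2 was examined through the spread of F2 animals, without genotypes. For strain-called transcripts the F2 variance, with sex and batch in the fit, was 1.76 times the variance within the 6 groups of parental and F1 animals (median; quartiles 1.25 and 2.60). The ratio was 1.32 for uncalled transcripts of matched mean expression, and 1.26 for uncalled transcripts matched also on the variance within groups, which favours calls when it is low. Among the 575 called transcripts with at least 0.5 log2 units between the strains, 127 (22.1%) had a ratio over 4, against 1.0% of uncalled transcripts. These shares were not matched on mean expression or on the variance within groups. A low variance within groups raises the ratio and favours calls, so part of this contrast may come from the selection.

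The parental levels of 31 strain-called transcripts lay at least 8 SD of the within-group spread apart, with an F1 level in the middle part of the interval. The F2 animals could be set against these levels after sex and batch effects were subtracted. The median share of F2 animals nearest the F1 level was 56.0%, with 23.8% nearest the MRL and 22.7% nearest the SM level. A chi-square test against the ratio 1:2:1, with Benjamini-Hochberg adjustment over the 31, did not separate 15 transcripts from that ratio and separated 16, of which 15 had over 50% of animals nearest F1. Where the F1 level lies close to 1 parent, assignment to the nearest level can by itself depart from 1:2:1. In ENSMUST00000054791_at, F1 stood at 6.94 against 7.13 in MRL and 6.38 in SM, with a within-group SD of 0.09. How many of the 16 departures come from this was not tested. For ENSMUST00000084342_at, at 8.36 in MRL, 9.91 in F1 and 10.73 in SM, 73 F2 animals were nearest the MRL, 133 the F1 and 76 the SM level (adjusted p = 0.763). For ENSMUST00000044547_at the numbers were 56, 169 and 57 (adjusted p = 0.00849), and the F2 animals near the SM level stood apart from the rest. Transcripts of the same gene share probes, and the 31 fell into 21 sets with correlations over 0.8 in F2, so they are not 31 separate loci.

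**Figure D4:**
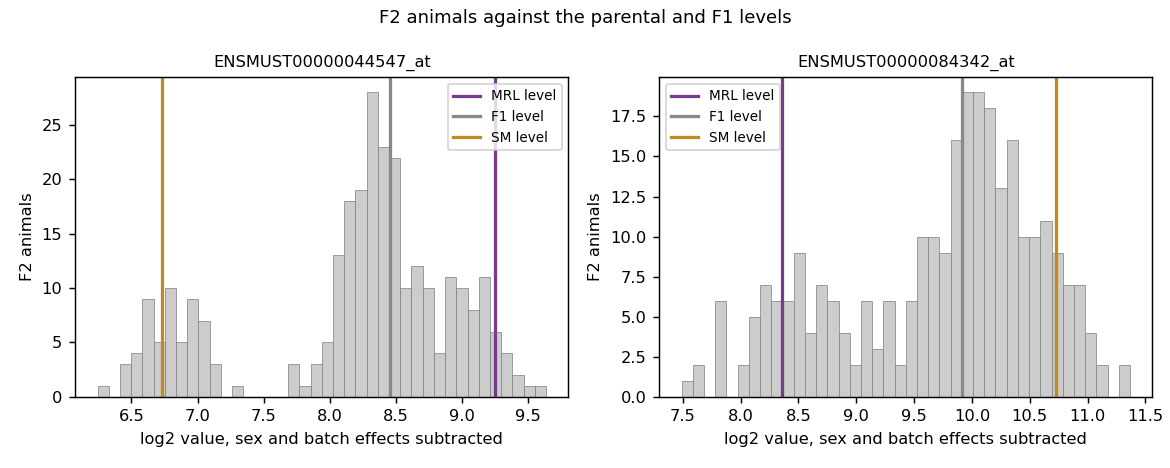
Number of F2 animals (n = 282) by log2 value, after sex and batch effects were subtracted, for the transcripts with the widest separation of parental levels in each direction. Vertical lines mark the mean levels of the 6 MRL, 6 F1 and 6 SM animals. F2 animals spread over the whole parental interval, with 133 and 169 of 282 nearest the F1 level.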

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

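The tests of array spread slopes, of batch as a fixed term, of F2 spread by sex, of all 200 splits and of the interaction without replicate 1146 were chosen after the interaction had been seen. Strain differences that differed between females and males were picked out by the interaction test, which 76 transcripts passed. Those with the greatest differences were ENSMUST00000086148_at at 2.88 and ENSMUST00000108522_at at 2.70 log2 units, both highest in SM females, and ENSMUST00000095784_at at -1.83 and ENSMUST00000027467_at at -1.64, both highest in SM males. ENSMUST00000086148_at did not pass with the trend and robust options (adjusted p = 0.0594), and ENSMUST00000108522_at did not pass with batch as a random block (2.64 log2 units). ENSMUST00000108522_at also did not pass without MRL female replicate 1, 2 or 3 (adjusted p of 0.0869, 0.108 and 0.0915), SM female replicate 2 or 3 (0.104 and 0.092), MRL male replicate 6, 7 or 8 (0.0793, 0.0981 and 0.0851) or SM male replicate 6 or 7 (0.116 and 0.0592).

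Array spread, batch and chance were set against a sex-dependent strain effect for these 76 transcripts. Subtracting the array spread slope left 59 calls and a median of 86.8% of the original difference (quartiles 73.6% and 100.1%), and quantile normalization left 94 calls and 96.0%, which argues against array spread as the whole cause, although only 42 and 62 of the original 76 were still called and the loss of the others was not explained. Subtracting batch effects estimated in F2 left 55 calls, 45 of them among the 76, and 97.9% of the difference, and with batch as a fixed term 35 calls were left, 15 among the 76, while all 76 kept their sign and a median of 95.8% of the difference (quartiles 87.7% and 110.8%), which argues against batch as the whole cause. Of 100 splits of the parental animals within sex, 2 gave as many calls, the real one included, with 170 as the highest other, but over all 200 splits 12 (6%) did, so chance is not excluded; 11 of these exchange most strain labels in 1 sex, which puts the strain difference itself into the interaction, and among the 100 splits that do not, the real one gave the most, with 53 as the highest other. Strain alleles that act in 1 sex may add to F2 spread in that sex: the F2 SD was larger in the sex with the greater strain difference in 76.3% of the 76, against 58.4% of other strain-called transcripts, but the ratio of F2 to parental variance was 2.90 there and 2.49 in the other sex, so this explanation stays open.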

How the results depend on the processing

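The array spread corrections, batch as a fixed term, the males of the shared batches and the fits without doubtful libraries were chosen after the data were seen. No named transcript changed sign under the alternatives run, but the majority direction of some counts turned. Means over the rows of a gene were not run, since rows were not assigned to genes, and the setting with every row as its own feature is the one reported. The strain difference over both sexes and the sex difference in the parental and F1 animals stayed within 1.5 times their counts under the alternatives run except batch as a fixed term, with 2947 to 3773 and 2318 to 3723 transcripts when animals were left out in turn. Leaving out animals gave 1361 to 2972 for the strain difference in females, 1233 to 2418 in males, 28 to 225 for the interaction, 6 to 139 for F1 against the parental mean and 1.76 to 1.89 for the F2 variance ratio. Fewer animals lower the power of a test, which would not raise a count, and the cause of the rises was not tested.

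The interaction gave 50 calls among transcripts above the median mean, where fewer were tested. In the fit of all animals with batch it gave 25, and the strain difference 1501 in females and 1139 in males; F2 animals set the spread there. With only the compared groups the interaction gave 266. F1 against the parental mean gave 8 after centring, 20 with the trend and robust options and 7 with F2 batch effects subtracted; the cause was not tested. The F2 sex difference gave a median of 2788 within batches and 2416 in draws of 9 males and 9 females (1751 to 3925), where fewer animals were tested. The F2 variance ratio was 1.86 without batch adjustment and 1.70 after the array spread slope was subtracted. The F2 segregation share stayed between 51.1% and 56.0%.

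With batch as a fixed term, which leaves 3 residual degrees of freedom, the counts were 2249 for the strain difference over both sexes, 980 in females, 1220 in males, 35 for the interaction, 30 for F1 against the parental mean and 941 for the sex difference in the parental and F1 animals; the cause was not tested further.

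The share of calls higher in MRL among males was 60.5% after quantile normalization in place of 72.5%. For the interaction the share higher fell to 40.7% from 59.2% with the array spread slope subtracted, and for F1 against the parental mean to 28.6% from 53.8%, or to 40% after quantile normalization.

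Animal numbers are shared between MRL and SM. Deviations of same-numbered animals correlated with r of -0.085, 0.013 and 0.019 in females and 0.163, 0.219 and -0.038 in males. Animals with different numbers ran from -0.080 to 0.072 in females and from -0.284 to 0.153 in males. With 3 animals per group, these values do not decide whether the numbers pair the animals. With the replicate block, fitted in the compared groups only, the counts were 3804, 2197, 2779 and 265 for the strain difference over both sexes, in females, in males and for the interaction. Of the named transcripts, 553 values under alternatives kept their direction and side of the threshold and 28 kept the direction without passing. Signal over background was not examined here, so a log2 difference from a group with low values depends on the background level of the arrays.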

Other observations

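The linkage test, the tests of a swap and of mixed RNA, the simulated mixtures, the separation of 4 SD for the X-linked pattern, the comparison with the mirrored pattern, the limit on spread for X-linkage, the test of replicate 2295, the likeness of replicates 2116 and 2308 and the further draws of splits were chosen after the results had been seen. Of the 76 transcripts with a strain by sex interaction, 10 differed between F2 males and females by at least 0.5 log2 units; a sex difference in at least 1 strain is part of an interaction, so no share for unrelated lists applies. ENSMUST00000095784_at, highest in SM males among the parents, spread over 1.00 log2 units (SD, n = 147) in F2 males and 0.09 (SD, n = 135) in F2 females. ENSMUST00000086148_at spread over 1.52 in F2 females and 0.42 in F2 males, or 0.16 without male replicate 2308, which lies between the sexes and stood at 10.33.

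Among uncalled transcripts, 322 of 30854 had an F2 variance over 4 times that of the 18 animals, beside 330 of the 3552 strain-called ones, without matching. ENSMUST00000099390_at was below both parents in F1 and ran from 5.65 to 8.72 in F2 males, a wider range than the parental animals at 7.94 to 8.41. In ENSMUST00000047134_at, F1 female replicate 1145 stood at 6.04, near the SM level of 6.32, while F1 females 1149 and 1150 stood at 7.96.

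Transcripts with clear parental differences moved together in F2 in a fixed orientation. Of 89 strain-called transcripts with parental levels at least 6 SD apart, 64 remained when 1 was kept of each set with a correlation over 0.9. After each was turned so that the MRL level was high, 95 pairs correlated over 0.3 across F2 animals and 3 under -0.3, so that 96.9% of these pairs were positive, while 55.6% of all 2016 pairs were. Linked loci carried together from 1 parent may give this orientation, but so would 1 segregating regulator of several transcripts, or transcripts of 1 gene among the pairs, and these were not separated here.

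A pattern of X-linked inheritance was looked for, since F1 males carry the X chromosome of an MRL mother. A separation of 6 SD between the parental levels gave no transcript, and 4 SD was used after 3, 4, 5 and 6 SD had been looked at. With replicate 1146 left out, 6 transcripts were at the MRL level in F1 males and midway in F1 females, and 6 showed the mirrored pattern with F1 males at the SM level, which this inheritance would not give. In F2 females a median of 20% of animals were nearest the SM level (4.4% to 29.6%), which X-linked inheritance would leave empty, and 42.5% of F2 males were midway (5.4% to 55.1%). None of the 6 met both limits set for X-linkage, under 10% of females at the SM level and under 25% of males midway. The median of 20% met the limit set beforehand against X-linkage, 20% or more, which argues against it for the 6 as a set. That median lay exactly on the limit, and the transcripts spread to either side. By a limit on spread, added after the values were seen, the question would stay open.

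The library labelled F1 male replicate 1146 had the sex transcripts of a female, with ENSMUST00000082214_at at 11.79. A swap within the F1 generation would need a labelled female with male transcripts, and the highest score among the F1 females was -1.09, which argues against it. A female animal under a male label and a male animal with female-type liver expression cannot be told apart here: its mean position at the 6 transcripts above was 0.66, between F1 females and the other F1 males, and below the limit of 0.75 set beforehand for a female, but the mirrored pattern was as frequent, so these transcripts were not shown to follow the X chromosome and the test decides nothing. A swap with an animal outside the F1 arrays was not tested. Rows were not assigned to chromosomes, so transcripts of the Y chromosome, which only a male animal carries, were not singled out for this library.

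A mixture of male and female RNA was weighed for the 4 F2 libraries labelled female and 1 labelled male that lie between the sexes. The male share from male-high transcripts and the female share from female-high transcripts summed to between 0.8 and 1.2 in 3 of the 5 libraries, at 0.86, 0.97 and 1.08 in replicates 2293, 2116 and 2308, and to 0.68 and 0.58 in replicates 2295 and 2122, below the 5th percentile of 0.80 in other F2 libraries. For replicate 2295, 15 of 51 sex transcripts lay outside what any share of male and female RNA from the other F2 libraries could give, above the highest of those libraries at 9, which argues against a mixture there; in ENSMUST00000092597_at it stood at 5.67, the level of males. The number was 0 at male shares of 0.48 to 0.54 in replicate 2116, 0.49 to 0.51 in 2308 and only 0.01 to 0.03 in 2293, and 9 at 0.03 in 2122, above the 95th percentile of 3.2 and equal to the highest other library, so a mixture stays open at about equal shares for 2116 and 2308, at a small male share for 2293, and undecided for 2122. The other explanation, 1 animal with intermediate sex-dependent expression in each library, was tested by the distance to the nearest parental or F1 level at segregating transcripts, and 0 of the 5 lay above the 95th percentile, but only 4.3% of 1000 simulated equal mixtures did, so that test decides nothing.

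Like replicate 2295, female replicate 2116 (male share 0.50, female share 0.47) and male replicate 2308 (0.53 and 0.55) were run in batch 10. Over all transcripts, which are not independent replicates, 5 of 39621 pairs of F2 libraries correlated as highly as this pair (r = 0.995), but among transcripts without a called sex difference, with sex and batch in the fit, 9388 pairs did (r = 0.10). Whether each holds RNA of the other was not settled by these values. In ENSMUST00000082214_at, male replicate 2308 stood at 11.35 and female replicates 2293, 2116, 2295 and 2122 at 11.56, 11.33, 11.27 and 11.74, against 6.18 ± 0.61 (SD, n = 147) in F2 males. In ENSMUST00000084343_at, which was 6.32 ± 0.92 (SD, n = 135) in F2 females and 11.22 ± 0.18 in F2 males, they stood at 10.93, 7.65, 10.89, 10.10 and 8.65 in the same order.

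Whether chance could give as many calls was asked with other splits. For the strain difference over both sexes 1 of 100 splits, the real one, gave 3552 calls, and the highest other gave 897, or 1217 over all 200 splits. For F1 against the parental mean 1 of 100 gave 13 calls, with 11 as the highest other. In a larger draw 21 of 1000 (2.1%) gave as many, with 8381 as the highest other. These splits exchange MRL, SM and F1 labels together within sex, so they can put the strain difference into this contrast. Which groupings gave the high counts was not examined. For the sex difference it was 1 of 100 in the parental and F1 animals (3109 calls, highest other 735) and 1 of 100 in F2 (15478 calls, highest other 3450). Chance can be excluded at that level for the strain difference over both sexes and for the sex difference in both sets of animals. For F1 against the parental mean the splits, which also move the strain difference, do not decide it. The highest other depends on the draw: a second draw of F2 splits had 127 as its highest. The splits for F1 and for the sex difference in the parental and F1 animals are also a second draw, made to leave out repeats, and the first had the same highest others, 11 and 735. For the strain difference in females and in males there are 10 splits each, too few for a share under 0.05; the real split gave 2761 and 2225 calls and the highest other gave 0 in both.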
